A study of Homo sapiens with 4 samples.

How the data were processed

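The data are 4 arrays of normal human astrocytes, 1 for each of media, LpL, TGRL and TGRL+LpL. Per the series' design text, RNA of each group was pooled (n = 3 per group), and per the labels' protocols the pooled RNA was amplified and biotin-labelled with the Affymetrix 3′ IVT Express kit. The values used are the deposited intensity of each probe set, a signal on a linear scale from 0.0330 to 19795. The authors used Affymetrix Expression Console, per the submitters' processing notes. Its version, the method that summarised probes into probe sets and the scaling target are not given in the sources used here. The deposited intensities themselves show a common scale, with a mean of 500.1 on each of the 4 arrays after 2% of the values were trimmed at each end, so the authors' values were already scaled. No detection calls were used, and how far a dim signal lies above background is therefore unknown. Pooling removes the spread between isolates, so neither that spread nor an outlying isolate can be seen.

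Signals were turned into log2(signal + 16), the branch planned for linear values, and a log2 difference or fold on that scale understates the difference of dim genes. Of 22277 probe sets, 19070 were annotated to exactly 1 gene, 1043 to several and 2164 had no gene listed, and only the first kind named a gene. Symbols were updated through Entrez identifiers to the names of the RefSeq table of assembly GRCh38.p14, which matched 19058 probe sets. No coordinates are given, because the build behind the array annotation is not given in the sources used here. The 62 control probe sets served for checks, and those annotated to 1 gene, such as ACTB and GAPDH, also entered the gene table. A gene's value was that of its probe set with the highest mean over the 4 arrays. A gene was compared where its highest value reached the median of all probe set values, a signal of 85.8, which kept 7194 of 11939 genes. Genes on the Y chromosome and XIST were left out.

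There were 6 comparisons, namely TGRL+LpL minus media, minus TGRL and minus LpL, TGRL minus media, LpL minus media, and the interaction. With 1 array per group no test was run, and the counts are of genes at least 2-fold apart. Unchanged arrays were simulated 100 times from the disagreement between probe sets of 1 gene in LpL minus media, the smallest of the 6, which gave a mean of 0.08 to 0.14 genes at least 2-fold apart per comparison and 11.6 in the interaction. With the larger spread of each comparison itself, the mean was 1.94 for TGRL+LpL minus media, 0.44 for TGRL+LpL minus TGRL, 3.80 for TGRL+LpL minus LpL and 0.16 for TGRL minus media. These simulations hold no noise between cultures or RNA pools. For each of 35 gene lists, written before the data were examined, as were the filter, the thresholds, the rule for named genes and the alternatives, the median log2 difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list was called high at the 98th percentile or above and low at the 2nd or below, if 5 or more members were compared, which held for 32 lists. A percentile describes these arrays and is not a p-value.

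Genes were named by a rule. For TGRL+LpL minus media the 12 largest and the 12 smallest differences were named, for each other comparison the 6 largest and the 6 smallest, and from each list the 4 members with the largest absolute difference in TGRL+LpL minus media. A fixed set was named where its genes passed the filter, which GFAP did not (ATF3, DDIT3, JUN, FOS, EGR1, IL6, CXCL8, PTGS2, PLIN2, ANGPTL4, HMOX1, HMGCS1, GFAP, GAPDH and ACTB among them). This gave 168 genes, of which the text prints those it needs, and a gene outside the rule is said to have been chosen after its values were seen.

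The arrays were compared first. No probe set values were identical on all 4 arrays, and Pearson's r of log2 signal across probe sets lay between 0.986 and 0.990 for pairs of arrays. The 18 bacterial spike-in probe sets differed between arrays by at most 0.29 log2, with a median gap of 0.21. The 3′ to 5′ signal ratio was 1.34, 1.46, 1.53 and 1.61 for ACTB in media, LpL, TGRL and TGRL+LpL, and 0.974, 0.957, 0.933 and 0.901 for GAPDH. The test of RNA integrity was limited to these 2 transcripts after its result was known, its outcome was undecided before and after that step, and 1 other control transcript is not reported here. The labels give no array batch or scan date, so a batch could not be looked for.

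The steps were tested on simulated data for TGRL+LpL minus media with the 7194 genes and the noise of LpL minus media. Of 50 genes set 3-fold apart and 50 set 4-fold apart, 100% passed the 2-fold line, of 50 set 2-fold apart 62% did, and of 50 set 1.5-fold apart 0% did, as did 0% of 6994 unchanged genes. Lists of 20 genes shifted by 0.3 log2 were called in 100% of 100 draws and unshifted lists in 5%. The alternatives tried were each array centred on its median, quantile normalisation, no filter, a filter at the 75th percentile, the mean over a gene's probe sets, leaving out probe sets with the suffixes _x_at and _s_at, which mark possible cross-hybridisation or a match to several transcripts, a line at 1.5-fold, a pseudocount of 1, and random lists not matched on expression. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.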

Results

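Messenger RNA was measured in normal human astrocytes, primary glial cells of the brain, after 3 h in 1 of 4 conditions. The conditions were culture medium alone (media), lipoprotein lipase at 2 U/mL (LpL), triglyceride-rich lipoprotein at 150 mg/dL (TGRL), and TGRL at the same dose with LpL at the same activity. Lipoprotein lipase is the enzyme that releases fatty acids from lipoprotein triglyceride, so the last condition holds TGRL lipolysis products. Total RNA isolates of each condition (n = 3) were pooled and put on 1 Affymetrix array, which gave 4 arrays with no replicates. Every difference below therefore compares single arrays, has no replicate check and no p-value, and the number of arrays limits the precision. Median probe set signal was 84.4 in media, 85.1 in LpL, 85.3 in TGRL and 88.3 in TGRL+LpL. The array of TGRL+LpL was the most compressed at the bright end, with a 99th percentile of 9552 against 10617, 11121 and 10918 in media, LpL and TGRL. The only measure of error at hand is how far probe sets of 1 gene disagree. Their pooled SD of the log2 difference lay between 0.20 for LpL minus media and 0.29 for the interaction, over 5578 probe sets of 2275 genes, and it covers the arrays and not the cultures. After the filter on dim probe sets, 7194 genes were compared.

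The main question was how lipolysis products act on astrocytes, which sets TGRL+LpL against media. Chemokines stood at the top. CXCL2, a chemokine that attracts neutrophils (Entrez gene 2920), had a signal of 6220 with TGRL+LpL and 82.6 in media, a log2 difference of 5.98 (63.2-fold). Its relatives CXCL3 (Entrez gene 2921, 39.6-fold) and CXCL1 (Entrez gene 2919, 11.8-fold) and the lymphocyte and dendritic cell attractant CCL20 (Entrez gene 6364, 8.70-fold) were also higher. Beside them stood the orphan nuclear receptors NR4A2 (16.7-fold) and NR4A3 (8.19-fold), the transcription factor KLF4 (8.95-fold) and the stress genes DDIT4, CHAC1, DDIT3 and ATF3. Over all probe sets of these genes the log2 difference of NR4A3 was 2.05 against 3.03, and that of KLF4 2.46 against 3.16. DDIT3, which encodes the stress transcription factor CHOP, had a signal of 2187 against 318 (log2 difference 2.72), and ATF3, a stress-induced transcription factor, 1462 against 228 (2.60).

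In all, 156 genes were at least 2-fold apart, 130 of them higher and 26 lower with TGRL+LpL (113 and 41 with each array centred on its median). Of the genes named by rank, AVPI1 was also higher (log2 difference 2.56). Among the lower genes, BMP4, a bone morphogenetic protein, had a signal of 14.2 against 104 (log2 difference −1.99), and a signal under the pseudocount of 16 leaves the size of its differences and its rank uncertain. SOX9, a transcription factor of the astrocyte lineage, had a signal of 379 against 1090 (−1.49). SMAD7, an inhibitor of TGF-beta signalling, was at −1.54, and SNAI2, a transcriptional repressor of the Snail family, at −1.30 with a signal of 1041 against 2585. TXNIP, which binds thioredoxin and restrains glucose uptake, was at −1.49. PALM was at −1.68, EEF2KMT at −1.63, TRIB2 at −1.41, RRS1 at −1.37 and PRR5L at −1.31. RGS3 at −1.25 and DYRK2 at −1.30 also ranked among the lowest, but the mean over all their probe sets was −0.13 and −0.76.

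**Figure D1:**
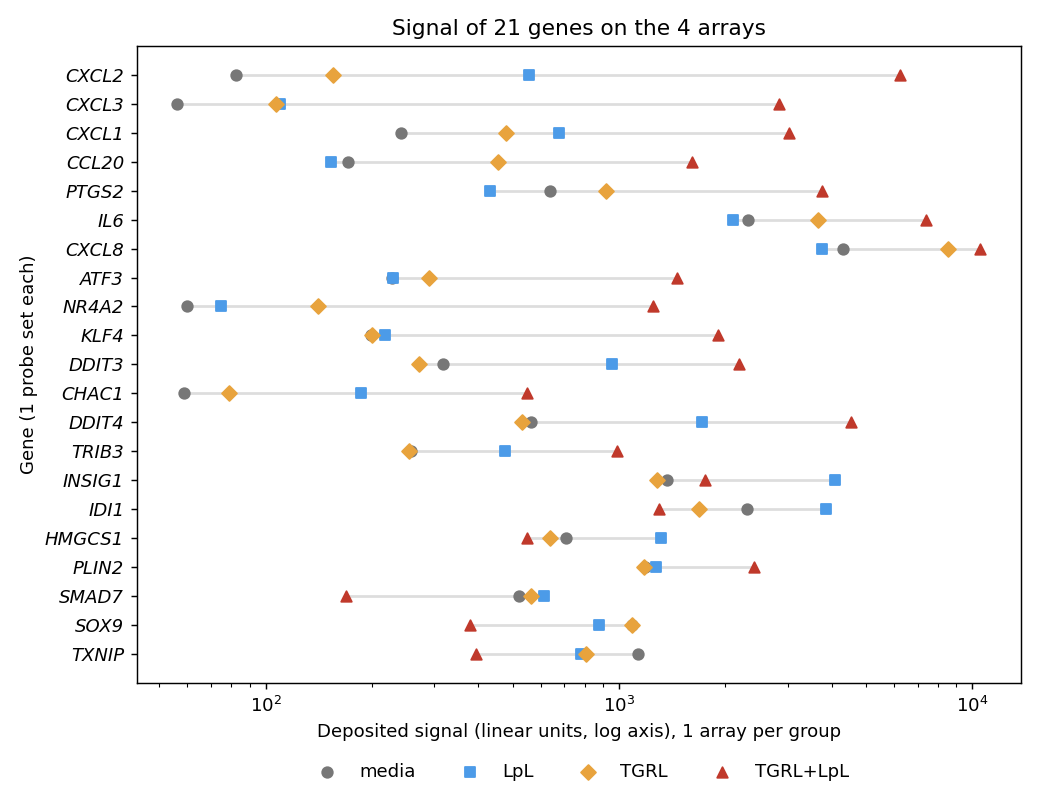
Deposited signal of named genes on the 4 arrays, 1 point per array, on a logarithmic axis without the pseudocount. CXCL2 lies at a signal of 82.6 in media, 155 with TGRL, 555 with LpL and 6220 with TGRL+LpL, while SOX9 lies at 1090, 1090, 875 and 379.

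Gene lists fixed in advance put numbers on these groups. In the inflammatory list of cytokines, chemokines and NF-kB targets, 12 of the 25 compared members were at least 2-fold higher and 0 lower, with 23 above 0 and a median log2 difference of 0.88. PTGS2, the inducible cyclooxygenase, was at 2.52, IL6 at 1.67 with a signal of 7389 against 2312, and CXCL8 at 1.28. All 24 compared genes of the integrated stress response, the program that limits translation and induces amino acid genes, were above 0, with 8 at least 2-fold higher and a median of 0.73. Among them TRIB3, a pseudokinase induced by CHOP, was at 1.88, the cystine transporter SLC7A11 at 1.83 and the lipoprotein receptor VLDLR at 1.08. Of 24 immediate early and AP-1 genes, 8 were at least 2-fold higher and 1 lower, with a median of 0.67, and FOS was at 1.81 while EGR1 was at 0.82 and JUN at 0.32 (0.60 without probe sets that may cross-hybridise). Of 12 MAPK phosphatases and feedback inhibitors, DUSP10 (1.43), DUSP2 (1.39), DUSP4 (1.39) and DUSP5 (1.04) were at least 2-fold higher, with a list median of 0.31. The median of neuron markers was 0.32 over 8 genes, led by the vesicle fusion gene SNAP25 at 1.32 (0.84 over both probe sets) and the neurofilament gene NEFM at 0.60, while the tubulin gene TUBB3 was at −0.74.

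The first 3 of these lists lay above all 10000 random lists matched on expression, the MAPK list at the 99.8th percentile and the neuron list at the 98.7th. Metallothioneins, small proteins that bind zinc, were low as a group with a median of −0.35 over 6 genes, at the 0.03rd percentile, with MT1E at −0.48 and MT1X at −0.35. All 6 are read by probe sets whose suffix marks possible cross-hybridisation, so they are not separate readings, unlike the genes of the random lists. The 6 lists named here were the ones called among the 32 that could be ranked. Lists of randomly drawn genes would give 0.64 each way, a rate that does not allow for list members that vary together. The MAPK and neuron calls ended with another filter or without probe sets that may cross-hybridise. CXCL2 is read by a probe set whose suffix marks possible cross-hybridisation, so how signal divides between CXCL1, CXCL2 and CXCL3 is uncertain.

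Other stress and lipid programs were not called as groups in this comparison by the main analysis. The unfolded protein response list had a median of −0.07 over 18 genes, although XBP1 was at 0.83, DNAJB9 at 0.80 (1.25 without probe sets that may cross-hybridise) and HERPUD1 at 0.51, against SDF2L1 at −0.69. The NRF2 antioxidant list had a median of −0.06, with HMOX1, heme oxygenase 1, at 1.59 and MAFG at 0.97. The median of PPAR targets was 0.00, with the fatty acid importer of mitochondria CPT1A at 0.68 (0.17 over its 4 probe sets, which differ in sign) and ANGPTL4, an inhibitor of LpL, at −0.50. Lipid droplet genes had a median of 0.07, and PLIN2, a coat protein of lipid droplets, was at 1.01 with a signal of 2406 against 1185, but at 0.69 over both its probe sets. SREBP2 targets had a median of −0.15, with IDI1 at −0.82 and NSDHL at −0.94. Fatty acid synthesis lay at 0.09, LXR targets at 0.08 with NPC1 at 0.57, and lipoprotein and scavenger receptors at 0.02 with OLR1 at 0.83. Heat shock genes lay at −0.17, interferon genes at 0.05, apoptosis genes at −0.07, p53 targets at 0.09 and TGF-beta genes at −0.12. Growth factors went both ways around a median of −0.15, with BMP2 at 1.23, GDF15 at 1.24 and VEGFA at 1.23 (0.80 over all its probe sets). Hypoxia and glycolysis genes lay at −0.13, with the glucose transporter SLC2A3 at 1.08 and the vasodilator peptide gene ADM at 1.42. Medians of G2/M and of S phase genes were both −0.11, and that of oxidative phosphorylation was −0.11. Ribosomal proteins lay at −0.17, reactive oxygen enzymes at −0.15 and matrix genes at −0.04 (0.09 and called high after quantile normalisation). Cell type lists lay at −0.05 for astrocytes, −0.14 for reactive astrocytes, −0.12 for the oligodendrocyte lineage and −0.17 for fibroblasts and pericytes. Housekeeping genes lay at −0.05, with GAPDH at −0.01 and ACTB at −0.20. Other probe sets of these genes went down to −0.21 for GAPDH and −0.47 for ACTB. No gene of the microglia list (0 of 14) or of the blood cell and hepatocyte list (0 of 14) passed the filter, and 4 of 13 endothelial genes did, too few to rank.

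**Figure D2:**
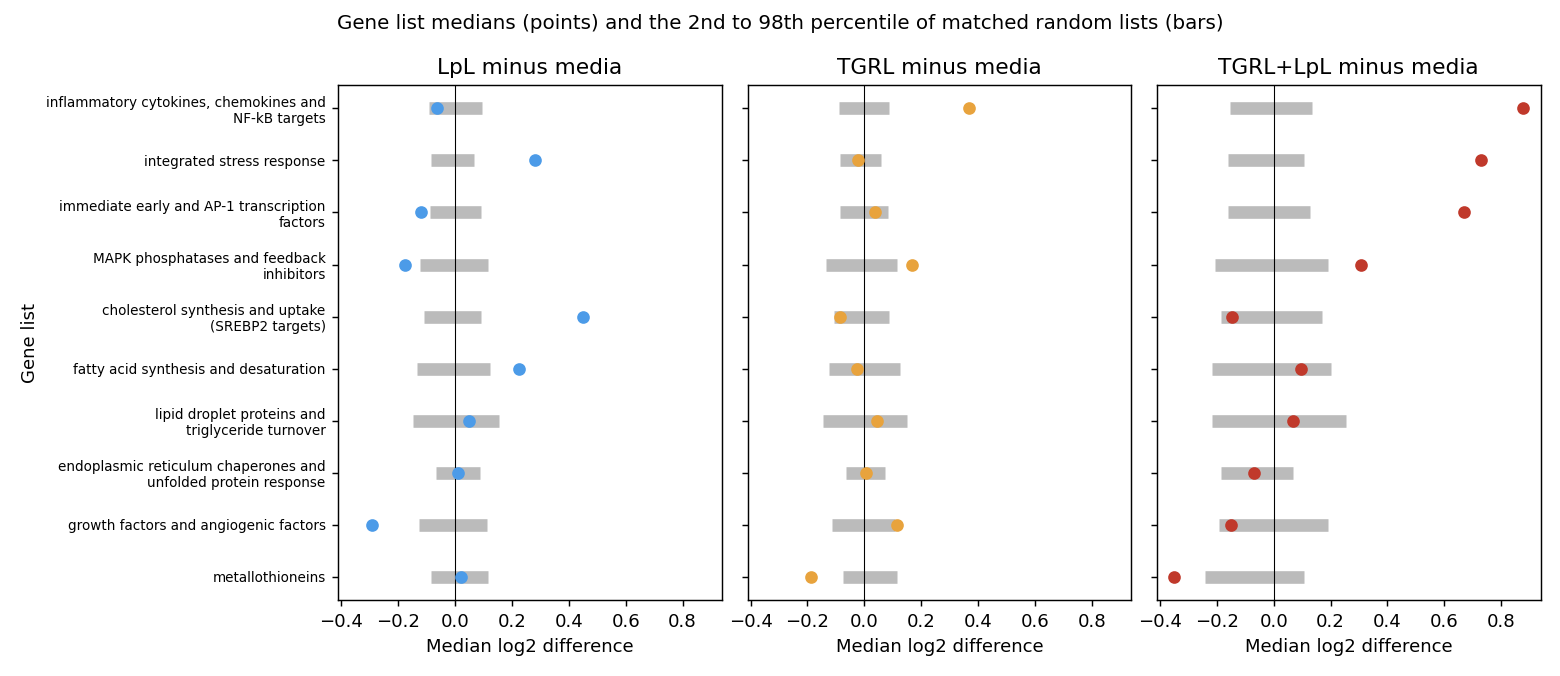
Median log2 difference of 10 gene lists (points) in LpL, TGRL and TGRL+LpL against media, with bars from the 2nd to the 98th percentile of 10000 random lists matched on expression. Inflammatory genes lie at −0.06, 0.37 and 0.88, integrated stress response genes at 0.28, −0.02 and 0.73, and SREBP2 targets at 0.45, −0.09 and −0.15.

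Setting TGRL+LpL against TGRL asks what the enzyme adds to the lipoprotein at the same dose, and it does not separate lipolysis from other effects of LpL. The same kinds of genes led. CXCL2 was 36.4-fold, CXCL3 23.2-fold, KLF4 8.89-fold, DDIT4 8.35-fold, NR4A2 8.07-fold and DDIT3 7.67-fold higher than with TGRL alone. ATF3 was 4.82-fold higher, with a signal of 1462 against 291, and PTGS2 4.02-fold. CXCL8 was at a log2 difference of 0.31, with a signal of 10533 against 8512 (0.62 over both probe sets), and IL6 was at 1.01. The lowest were SMAD7 (−1.64), SOX9 (−1.49), SMTN (−1.48), PALM (−1.46), TRIB2 (−1.36) and RGS3 (−1.33, but −0.68 over both probe sets).

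Over all genes, 116 were at least 2-fold apart between TGRL+LpL and TGRL, 89 higher and 27 lower. The integrated stress response had 9 of 24 genes at least 2-fold higher and a median of 0.70, and the inflammatory list 8 of 25 and a median of 0.52. Immediate early genes had a median of 0.48 and MAPK phosphatases of 0.30. LXR targets, genes of cholesterol efflux, had a median of 0.30 over 8 genes, with NPC1 at 0.61, and p53 targets one of 0.27 over 11 genes, with GADD45A at 0.56 and MDM2 at 0.54 but GADD45B at −0.64, and with 7 members above 0, 4 below and a mean of 0.14. Both were called high without any member reaching 2-fold. Growth factors were low, with a median of −0.34 over 14 genes, although BMP2 was at 1.47 and GDF15 at 1.23 (0.95 without probe sets that may cross-hybridise) while BMP4 was at −1.06. Reactive astrocyte genes had a median of −0.19 over 14 genes at the 1.49th percentile. The call of immediate early genes ended without probe sets that may cross-hybridise (median 0.11), and that of LXR targets without a filter (0.00). Those of MAPK phosphatases and reactive astrocyte genes ended with a stricter filter, the latter also after quantile normalisation (−0.09).

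TGRL+LpL against LpL asks what the lipoprotein adds to the enzyme. CXCL3 was 22.8-fold, CXCL2 10.9-fold, CCL20 9.62-fold, NR4A3 9.39-fold (log2 difference 3.23, but 2.29 over its probe sets) and PTGS2 8.41-fold higher than with LpL alone, and NR4A2 was at a log2 difference of 3.81. The cytokine IL11 was at 2.22, IL6 at 1.81, ATF3 at 2.59 and EGR1 at 1.32. Of the stress genes that were already higher with LpL than in media, DDIT4 at 1.39, DDIT3 at 1.18 and CHAC1 at 1.49 were also higher here, while HMOX1 was at 0.34. Cholesterol synthesis genes were lower with TGRL+LpL, with IDI1 at −1.56, HMGCS1, the synthase that precedes the rate-limiting step, at −1.24, INSIG1 at −1.21 and NSDHL at −1.17.

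In that comparison 125 genes were at least 2-fold apart, 99 higher and 26 lower. The lowest named genes were BMP4 (−2.22), TTC38 (−1.86, but −0.67 over its probe sets), SMAD7 (−1.76), PALM (−1.71), SNAI2 (−1.58) and IDI1. All 16 SREBP2 targets lay below 0, 5 of them at least 2-fold lower, with a median of −0.52 under all 10000 random lists. Medians were 0.67 for the inflammatory list, 0.55 for the integrated stress response, 0.70 for immediate early genes, of which 10 of 24 were at least 2-fold higher, 0.40 for MAPK phosphatases and 0.23 for growth factors, all called high. Low calls went to metallothioneins (−0.31), G2/M genes (−0.26), ribosomal proteins (−0.26) and fibroblast and pericyte markers (−0.26). The calls of ribosomal proteins and of fibroblast and pericyte markers ended after quantile normalisation (−0.02 and −0.13), and the growth factor median turned to −0.07 without a filter and to −0.04 without probe sets that may cross-hybridise.

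TGRL alone was closest to media of the 3 treatments. Only 14 genes were at least 2-fold apart, 10 higher and 4 lower. CCL20 was higher at a log2 difference of 1.33, with a signal of 454 against 171, and NR4A2 at 1.05. SLC30A1, a zinc exporter of the plasma membrane, was lower at −1.24, with a signal of 1060 against 2531. CXCL8 (0.98), CXCL1 (0.94), CXCL2 (0.79), IL6 (0.66) and PTGS2 (0.52) lay under the 2-fold line, and DDIT3 (−0.22), DDIT4 (−0.09) and ATF3 (0.33) near media.

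As a group, the inflammatory list was high with TGRL, with 24 of 25 genes above 0, 1 at least 2-fold higher and a median of 0.37 above all 10000 random lists. MAPK phosphatases (0.17), growth factors (0.12) and neuron markers (0.22) were also called high, and metallothioneins (−0.19), heat shock genes (−0.10) and interferon genes (−0.26) low. The integrated stress response had a median of −0.02 at the 39.0th percentile, and immediate early genes one of 0.04. The other genes at the ends of the ranking had signals between 14.7 and 368 on these arrays, with RPL10L at 1.53 (95.2 against 22.5), CYP3A4 at 1.37, FUT6 at 1.28, FAM204A at 1.25 and IKBKG at 1.21, and MYL10 at −2.28 (14.7 against 133), ERN2 at −1.29, EEF2KMT at −1.02, TTC38 at −0.97 and SLC2A8 at −0.96. Over all their probe sets CYP3A4 was at 0.60, FUT6 at 0.23, IKBKG at 0.58, TTC38 at −0.07 and MYL10 at −1.28, and IKBKG was at −0.05 without probe sets that may cross-hybridise. The MYL10 signal of 14.7 lies under the pseudocount, so the size and rank of its difference are uncertain. RPL10L and FAM204A were at least 2-fold higher than media, and MYL10 lower, with LpL and with TGRL+LpL as well. For these genes a departure of the 1 media array cannot be told apart from the treatments. The calls of heat shock genes, growth factors, neuron markers and interferon genes each ended under at least 1 other setting.

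LpL alone set genes of sterol synthesis apart from media, together with stress genes that were also higher with TGRL+LpL. INSIG1, which regulates sterol synthesis in the endoplasmic reticulum, had a signal of 4088 against 1370 (2.96-fold), HMGCS1 1311 against 708 (1.83-fold) and the desaturase FADS2 261 against 137 (log2 difference 0.86). DDIT4 was 3.00-fold, DDIT3 2.91-fold, CHAC1 2.70-fold and HMOX1 2.38-fold higher, and CXCL2 5.79-fold. IL11 (−1.40) and ANGPTL4 (−1.39) were lower, and ATF3 did not differ (0.00).

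With LpL, 41 genes were at least 2-fold apart from media, 27 higher and 14 lower. All 16 SREBP2 targets lay above 0 with a median of 0.45, and 22 of 24 integrated stress response genes with a median of 0.28, both above all 10000 random lists, with 1 and 3 genes at least 2-fold higher. Fatty acid synthesis (0.23), LXR targets (0.24) and G2/M genes (0.20) were also called high. Growth factors had a median of −0.29, MAPK phosphatases of −0.18, apoptosis genes of −0.14, immediate early genes of −0.12 and reactive astrocyte genes of −0.06, all called low, while the inflammatory list lay at −0.06 at the 6.64th percentile. Further genes at the top of the ranking were the fatty acid binding protein gene FABP3 (1.64, but 1.04 without probe sets that may cross-hybridise) and the receptor gene KIT (1.56, signal 691 against 224), and at the bottom SPDEF (−1.80, but −0.78 over its probe sets), HIVEP3 (−1.76), MYL10 (−1.63, but −0.97) and KLC2 (−1.34). SPDEF and HIVEP3 had LpL signals of 13.4 and 8.41, under the pseudocount, so the size and rank of their differences are uncertain. The fatty acid synthesis call ended with a stricter filter (median 0.04), over all probe sets (0.05) and without probe sets that may cross-hybridise (0.14), and each of the 4 low calls other than that of growth factors ended under at least 1 other setting.

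The interaction, the difference made by LpL with TGRL minus that made by LpL without it, shows where the combination departed from the sum of both treatments on the log2 scale. CXCL3 departed most, at 3.74, followed by KLF4 at 3.02 (2.32 over both probe sets), MYL10 at 2.88 (1.49 over both probe sets), NR4A2 at 2.75, CXCL2 at 2.65 and PTGS2 at 2.56. The TGRL signal of MYL10 lay under the pseudocount, so the size and rank of its departure are uncertain. FOS was at 2.21 and ATF3 at 2.26, where LpL differed from media by −0.25 and 0.00 for these genes while TGRL+LpL differed from TGRL by 1.96 and 2.27. SMAD7 was at −1.86, SNAI2 at −1.59, PALM, IMPDH1 and GDF5 each at −1.49 and STMN2 at −1.42. DDIT4, DDIT3 and CHAC1 departed less, at 1.48, 1.40 and 1.14.

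In the interaction 113 genes were at least 2-fold from 0, 72 upward and 41 downward (332 and 379 without a filter), against a mean of 11.6 and a highest count of 18 in 100 simulations of unchanged arrays. The simulated noise is the disagreement between probe sets and holds no difference between cultures or RNA pools. The excess is therefore no measure of what unchanged pools would give. Immediate early genes (0.67), the inflammatory list (0.50), the integrated stress response (0.47), interferon genes (0.36) and MAPK phosphatases (0.21) were called high and SREBP2 targets (−0.50) low. Counted array by array, 43 genes on the TGRL+LpL array were at least 2-fold above each of the other 3 arrays and 10 below each of them, against 2 and 5 for LpL, 1 and 2 for media and 0 and 1 for TGRL. The 43 include CXCL1, CXCL2, CXCL3, CCL20, IL6, PTGS2, ATF3, DDIT3, CHAC1, TRIB3, SLC7A11, FOS, NR4A2, NR4A3 and KLF4, and the 10 include BMP4, SMAD7, SNAI2, SOX9 and TRIB2. The call of MAPK phosphatases ended with a stricter filter, over all probe sets and without probe sets that may cross-hybridise.

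LpL minus media and TGRL+LpL minus TGRL share no array, so they give separate readings of what LpL does. Of the 27 genes at least 2-fold higher in the first and the 89 in the second, 14 were shared, where independent lists would share 0.334. They were DDIT3, DDIT4, CHAC1, CXCL1, CXCL2, HMOX1, ADM, AVPI1, DUSP10 and KIT, and EVI2A, GEM, MAF and UAP1L1, which were named after their values were seen. Across the 7194 genes, which are not independent replicates, Pearson's r between the differences was 0.34 and Spearman's rho 0.24. TGRL minus media and TGRL+LpL minus LpL share no array either, with r 0.39 and rho 0.38, and 3 genes were at least 2-fold higher in both, CCL20, NR4A2 and ANKRD12, the last named after its values were seen. Comparisons that share an array overlap by construction. TGRL+LpL minus media and TGRL+LpL minus TGRL shared 74 higher and 20 lower genes, where independent lists would share 1.61 and 0.0976. Part of that excess may come from the shared array. Simulated unchanged arrays shared 0, which is no reference, because they had almost no genes 2-fold apart. For this pair r was 0.82 against 0.50 for unchanged arrays, with a covariance of 0.112 against 0.0197. TGRL+LpL minus media and LpL minus media shared 17 higher genes against 0.488 for independent lists, and r was 0.41 against 0.50 for unchanged arrays, with a covariance of 0.0407 against 0.0198. For LpL minus media and TGRL minus media, which share the media array, r was 0.21 against 0.50 and the covariance 0.0117 against 0.0198. The simulated covariance is therefore no floor, and an excess over it is no measure of a shared response.

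**Figure D3:**
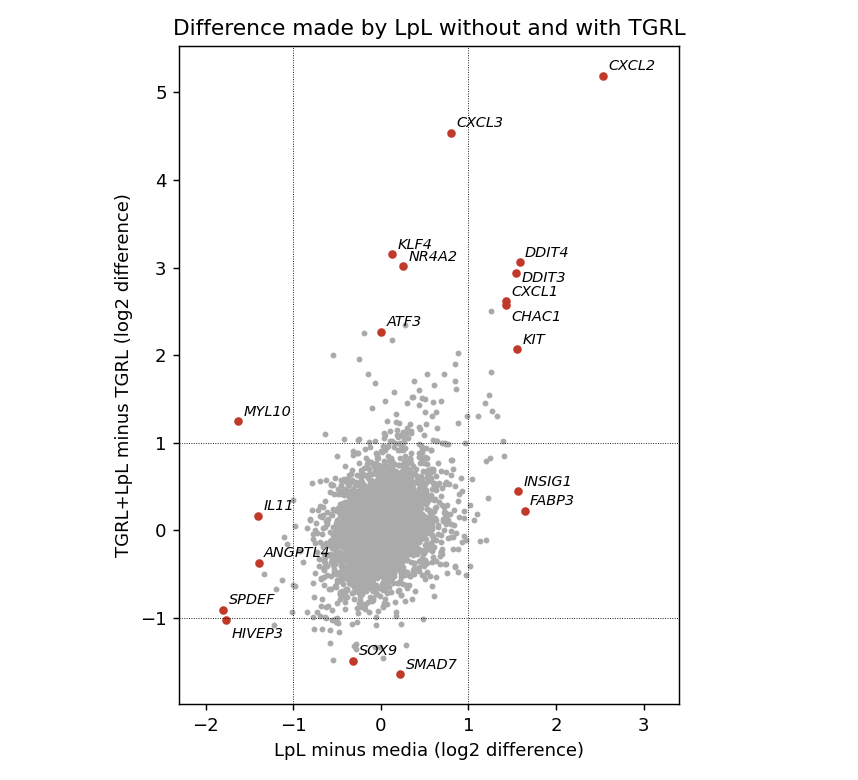
Log2 difference made by LpL without TGRL (LpL minus media, horizontal axis) and with TGRL (TGRL+LpL minus TGRL, vertical axis), 1 point per gene for 7194 genes, with dotted lines at 2-fold. DDIT3 lies at 1.54 and 2.94 and CXCL2 at 2.53 and 5.19, while ATF3 lies at 0.00 and 2.27 and INSIG1 at 1.57 and 0.45.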

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

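Among the tests of technical explanations below, those of other probe sets and of RNA integrity for the TGRL+LpL genes and both rank correlations between readings of LpL were chosen only after the result was seen. The biological explanation in each case is the treatment that the group's label names, and it stays untested because each group has 1 array.

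The first pattern is the 130 genes at least 2-fold higher with TGRL+LpL than in media, led by CXCL2, CXCL3 and NR4A2. Noise of single probe sets is argued against, because 49 other probe sets of 39 of these genes had a median log2 difference of 0.98 (SD 0.80), with 47 above 0. The scale of the arrays is argued against too, because 121 genes were at least 2-fold higher after quantile normalisation. RNA integrity cannot be told apart from the treatment, because 1 of 2 control transcripts, ACTB, had its highest 3′ to 5′ ratio on the TGRL+LpL array and the other, GAPDH, its lowest. Of the 130 genes, 17 were also at least 2-fold higher than in media with LpL alone, CXCL2 among them, and 5 with TGRL alone. A response of the cells to lipolysis products may account for part of the 130 genes, and it stays a hypothesis from single arrays.

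The next pattern is that integrated stress response genes such as DDIT3, DDIT4 and CHAC1 were higher with LpL alone than in media, in the absence of TGRL. Array scale is argued against by the list median of 0.29 after quantile normalisation. Noise of the LpL array alone is argued against by TGRL+LpL minus TGRL, which uses other arrays and ordered the 24 genes alike (Spearman's rho 0.69, reached by 0% of 10000 permutations of the genes). The genes are not independent replicates, so that share only describes these arrays. A difference in how the LpL cultures or RNA pool were handled is not addressed, because a stress response from it could order the genes alike. Noise of single probe sets cannot be excluded, since the 8 other probe sets of 6 of the genes had a median of only 0.11 (SD 0.42), though 7 were above 0. The enzyme, a component of its preparation or release of fatty acids from the medium could each give this pattern, and the 4 conditions hold no inactive enzyme to separate them.

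The last pattern is that all 16 SREBP2 targets were higher with LpL alone than in media and than with TGRL+LpL, 2 readings that share the LpL array. Array scale and single probe sets are argued against by a list median of 0.46 after quantile normalisation and of 0.48 (SD 0.52) over 10 other probe sets of 8 of the genes, with 9 above 0. Handling of the LpL RNA pool alone remains a candidate explanation, because TGRL+LpL minus TGRL had a list median of −0.12 and did not order these genes alike (rho 0.0912, reached by 37.9% of permutations). A supply of sterol by the lipoprotein that offsets the LpL difference would give the same low rho and stays open beside handling of the LpL RNA pool. With TGRL alone against media the list median was −0.09 and not called, but −0.16 and called low over all probe sets. A repeat of LpL alone, from new cultures, would tell these 2 explanations apart.

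Some results had opposite signs in the presence and the absence of the other treatment, and these differences were not tested. The immediate early list had a median log2 difference of −0.12 for LpL without TGRL and 0.48 with it, with an interaction median of 0.67. For MAPK phosphatases the medians were −0.18 and 0.30, with an interaction median of 0.21. The calls of both lists for LpL without TGRL and for LpL with it each ended under another setting. MYL10 was at −1.63 for LpL without TGRL and 1.25 with it, and at −2.28 for TGRL without LpL and 0.60 with it, an interaction of 2.88 at signals of at most 133. Over both its probe sets LpL alone was at −0.97, TGRL alone at −1.28 and the interaction at 1.49. FUT6, read here by only 1 of its 5 probe sets, was at 0.61 for LpL without TGRL and −0.75 with it (−1.36). STMN2, a neuronal gene, was at 0.83 for TGRL without LpL and −0.59 with it (−1.42). Outside the named genes, 24 of 1210 compared probe sets annotated to no gene or to several were at least 2-fold higher with TGRL+LpL than in media, and 4 were lower, a difference that was not tested.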

How the results depend on the processing

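No paired analysis was possible because each group had 1 array. Recomputing 304 results gave 1277 alternative values, of which 1150 were the same, meaning that list calls held, counts stayed within 1.5 times and gene differences moved by less than the spread between probe sets. Part of this agreement was fixed in advance, because a gene with 1 probe set cannot move when its probe sets are averaged. Lists called only under an alternative are not in the tally. No call of the inflammatory list, the integrated stress response list or SREBP2 targets ended under a setting tried. The cause of the moves below was not tested, except that fewer or more genes enter with another filter, threshold or choice of probe sets. Counts are given for TGRL+LpL minus media, minus TGRL and minus LpL, TGRL minus media, LpL minus media and the interaction in that order. They were 642, 469, 594, 156, 236 and 568 at 1.5-fold, 356, 346, 346, 235, 237 and 711 without a filter, and 92, 67, 75, 4, 17 and 52 with a filter at the 75th percentile. Without _x_at and _s_at probe sets, where 4336 genes were compared in place of 7194, they were 97 for TGRL+LpL minus media, 81 for TGRL+LpL minus LpL and 8 for TGRL minus media, and a pseudocount of 1 gave 30 for TGRL minus media. Scaling moved the split of TGRL minus media from 10 higher and 4 lower to 9 and 6 after quantile normalisation. Without a filter the interaction had 332 upward and 379 downward, so the larger side turned from 72 and 41. With each array centred on its median, TGRL+LpL minus media had 113 higher and 41 lower. Over 251 gene differences, neither scaling moved one by more than the spread between probe sets, the mean over probe sets moved 51, and leaving out _x_at and _s_at probe sets, where fewer had a value, left 149 the same, moved 7 and turned 2, IKBKG with TGRL (−0.0547) and NR4A1, chosen after its values were seen, with TGRL+LpL against media (−0.54). List calls that ended are given by their new median. Without a filter these were, for LpL minus media, immediate early −0.0689, MAPK phosphatases −0.12 and apoptosis −0.11; for TGRL minus media, heat shock −0.0666, interferon −0.0930 and growth factors 0.0643; for TGRL+LpL minus TGRL, LXR targets 0.00 (3.73e-05) and reactive astrocyte −0.12; neuron markers 0.20 in TGRL+LpL minus media. Growth factors in TGRL+LpL minus LpL turned to −0.0668. With the filter at the 75th percentile they were MAPK phosphatases 0.14 in TGRL+LpL minus media, 0.15 in TGRL+LpL minus TGRL, −0.12 in LpL minus media and 0.20 in the interaction, immediate early −0.0314 and fatty acid synthesis 0.0357 in LpL minus media, heat shock −0.0347 in TGRL minus media, reactive astrocyte −0.19 in TGRL+LpL minus TGRL and ribosomal proteins −0.26 in TGRL+LpL minus LpL. Over all probe sets they were MAPK phosphatases 0.20 in the interaction, apoptosis −0.0433, fatty acid synthesis 0.0461 and reactive astrocyte −0.0340 in LpL minus media, growth factors 0.0455 in TGRL minus media and 0.18 in TGRL+LpL minus LpL, and ribosomal proteins −0.20 there. Quantile normalisation gave −0.0200 for ribosomal proteins and −0.13 for fibroblast and pericyte markers in TGRL+LpL minus LpL, and −0.0903 for reactive astrocyte genes in TGRL+LpL minus TGRL. Unmatched random lists ended heat shock in TGRL minus media (−0.10) and reactive astrocyte in LpL minus media (−0.0573). Without _x_at and _s_at probe sets the medians were MAPK phosphatases −0.0612 in LpL minus media and 0.21 in the interaction, apoptosis −0.14, fatty acid synthesis 0.14 and reactive astrocyte −0.0712 in LpL minus media, immediate early 0.11 and reactive astrocyte −0.19 in TGRL+LpL minus TGRL, and neuron markers 0.32 in TGRL+LpL minus media. In TGRL minus media they were growth factors 0.12, heat shock −0.0288 and neuron markers 0.22, and in TGRL+LpL minus LpL growth factors −0.0356 (turned), ribosomal proteins −0.20 and fibroblast and pericyte markers −0.20. Some lists not called in the main analysis were called under an alternative, such as SREBP2 targets, low in TGRL+LpL minus media over all probe sets (−0.21) and without _x_at and _s_at probe sets (−0.25), and growth factors, low without those probe sets (−0.31). In the same comparison heat shock genes were low (−0.17) and matrix genes high (0.0950, against −0.04) after quantile normalisation, and p53 targets high (0.23) and fibroblast and pericyte markers low (−0.20) with the filter at the 75th percentile. SREBP2 targets were also low in TGRL minus media over all probe sets (−0.16) and in TGRL+LpL minus TGRL after quantile normalisation (−0.15). Having 1 array per group limits every comparison, and probe sets of 1 gene disagreed by a pooled SD of 0.29 below a mean signal of 500 and 0.21 above it in TGRL+LpL minus media.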

Other observations

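Several genes that handle zinc were lower with TGRL and with TGRL+LpL than in media, a group put together after its values were seen and not tested. SLC30A1, the zinc exporter, had a signal of 2531 in media, 1882 with LpL, 1060 with TGRL and 1450 with TGRL+LpL. MT1E was at 6390, 6362, 5360 and 4585, MT1X at 9197, 9737, 8234 and 7193, and MT2A at 11743, 12157, 11180 and 9498. MT1F and MT1H were also lower with TGRL and with TGRL+LpL than in media, at log2 differences of −0.41 and −0.34 for TGRL+LpL, while MT1G was higher at 0.24, as were MT3 (0.81) and MT1M (0.21), which lay under the filter. Each metallothionein that passed the filter is read only by probe sets whose suffix marks possible cross-hybridisation, so the family members are not separate readings. After quantile normalisation the list median of TGRL+LpL minus media was −0.29 against −0.35.

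Markers of cell identity were uneven. GFAP was in the fixed set and COL6A3 was named by the rule, while most of the other genes here were chosen after their values were seen. The astrocyte markers GFAP (2.72 to 4.45 over the 4 arrays), S100B (1.08 to 10.1), AQP4 (0.717 to 8.54), SLC1A3 (at most 72.2) and ALDH1L1 (25.2 to 55.5) all lay under the filter signal of 85.8. So did SLC1A2 (at most 18.3) and FGFR3 (at most 68.3). The gap junction gene GJA1 had signals of 11112 to 12749, the intermediate filament gene VIM 11032 to 14258, the hyaluronan receptor CD44 4502 to 5822 and glutamine synthetase, GLUL, 2206 to 2357. Of the measured members, 10 of 19 astrocyte markers and 14 of 15 fibroblast and pericyte markers passed the filter, with POSTN at 15207 in media. The median signal in media was 74.1 for the astrocyte list and 3691 for the fibroblast and pericyte list. Genes such as VIM and COL6A3 are expressed by several cell types, so these levels do not name the cells.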
